A study of Arabidopsis thaliana with 6 samples.

How the data were processed

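RNA-seq was analysed from 6 libraries of Arabidopsis thaliana seedlings. The labels assign 2 libraries to wild type (Col-0), 2 to the epl1a/b mutant, 1 to Col-0 kept in the dark and 1 to Col-0 in the light. The titles of both epl1a/b libraries begin with H4K5Ac, the name of a histone mark, which the wild type titles lack. Their other labels give total RNA and a transcriptomic library, as for wild type, and they were used as RNA-seq. All epl1a/b values rest on that reading. Per the labels' protocols, total RNA came from 2-week-old seedlings, and both a single-end 50 bp and a paired-end 150 bp strategy were used, without saying which library had which. The submitters' processing notes name HISAT2, featureCounts and edgeR and the TAIR10 build, with no version, role or setting. Whether counting used strand is not given in the sources used here. How long the dark treatment lasted is not given there either.

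The genotype comparison was deposited as a gene-level signal that is never negative: normalised read counts, per the file headers. The deposited columns summed to 19841584 and 19527327 for wild type replicates 1 and 2, and to 16677372 and 16668568 for epl1a/b replicates 1 and 2. The values are not whole. They were tested against edgeR's library-size equalisation, in which a gene's value depends on both libraries of its genotype. With relative library sizes and a common dispersion of 0.00642 fitted to the lowest values, the calculation could be inverted to whole read counts for 32548 of 32548 genes, 100% of them, with a tolerance of 1e-06. The recovered reads summed to 18796289, 18821439, 19088784 and 19067459. Depth per library was therefore almost equal, and the lower deposited totals of the mutant come from the scaling. The dark and light comparison was deposited as raw counts per gene, per the file headers, with 18798088 counts in the dark library and 27831231 in the light library. No column went unmapped, and both tables list 32548 genes of the nuclear chromosomes, with 0 plastid or mitochondrial genes.

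The plan fixed before the data were examined was edgeR's quasi-likelihood test for counts or estimated counts. It named limma-trend for the scaled units CPM, TPM, RPKM and FPKM, and did not name normalised counts. The choice between the tests was therefore made once the table was seen. Because the genotype table holds normalised values, limma 3.58.1 (R 4.3.3) was used, with eBayes trend and robust settings. It was run on log2(value + 1) of the 23658 genes with a value of at least 1 in at least 2 libraries. The model held genotype only. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Count tests on the recovered reads, with edgeR 4.0.16, DESeq2 1.42.0 and limma-voom, were added after seeing the data. The quasi-likelihood test called 5363 genes higher and 5581 lower there. Nothing in the labels says whether the 2 libraries of a genotype came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

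Named genes followed a rule fixed before the data were examined. It takes EPL1A, EPL1B, GLK1 and GLK2, then the 5 largest rises and 5 largest falls among called protein-coding genes with a mean of at least 10 and no overlap between genotypes. It adds up to 3 called members of each of the 6 lists closest to the study's subject and up to 2 of each other list. For dark against light it takes the 5 highest and 5 lowest ratios at a mean of at least 20 CPM, and the 2 largest ratios of each list at a mean of at least 5 CPM. Members named as exceptions within a list, YAF9A, YAF9B and PR1 included, and the genes named only in the closing section were chosen after their values were seen. The 19 gene lists, with 306 entries, were also fixed before. They were tested with camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 19 lists, and again with an estimated correlation. The latter takes its degrees of freedom from the few libraries, so it has little power here and a lost call decides little.

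The dark and light table has 1 library per condition, so no test was made. Counts were scaled with edgeR's TMM factors to CPM (counts scaled to a common library size), and log2 ratios used a prior count of 2 over the 21128 genes with at least 10 counts in total. The median of each list was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Ratios carry exact 95% Clopper-Pearson intervals, computed from the reads and the library sizes multiplied by their TMM factors. The ratio printed beside an interval includes the added value of 1 or the prior count, so it can lie away from the interval's centre. For a gene with 0 reads in a group, a bound was computed against 3 counts per library. Intervals and bounds cover counting error only. The tables were normalised separately, so no level is compared across them.

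Gene positions, products and overlaps came from TAIR10.1, in which 32548 of 32548 identifiers matched. A gene is described as uncertain where over 20% of its exon bases overlap another gene or over 20% of its 50-base words occur in another gene, a limit chosen after seeing the data. Overlap mattered for counting. Of 465 protein-coding genes with at least 95% of exon bases overlapped, 431 (92.7%) were listed at 0 in all 6 libraries, against 2596 of 22812 (11.4%) with at most 5% overlapped. LHCB1.5 and MYC2 are among the genes at 0 and were not tested.

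The tests were tried on simulated data with 200 changed genes among 32548, in 5 simulations of the genotype comparison. The inversion returned the simulated reads of 100% of genes. limma called 44.5% of genes changed 1.5-fold, 84.8% of those changed 2-fold and 97.3% of those changed 4-fold with the right sign. The changed genes were drawn only from genes above a minimum mean of recovered reads, so these shares do not cover genes with few reads. Of its calls there, 14.5% were false, against 17.9% for edgeR, so the nominal threshold of 0.05 was exceeded in both. Of the unchanged genes, limma called 0.11% and edgeR 0.17%. The share of false calls depends on how many genes change. In the real comparison 46.7% of tested genes were called, so the simulated shares do not carry over to those calls. Alternatives covered scaling, low-value filters, pseudocounts, a replicate block, a fold-change limit, the inter-gene correlation, prior counts and leaving out each replicate.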

Results

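Transcript levels were measured in 2-week-old seedlings of the Col-0 accession, a standard Arabidopsis wild type, and of a line labelled epl1a/b. EPL1A and EPL1B are the Arabidopsis relatives of Enhancer of polycomb, a subunit of the NuA4 histone acetyltransferase complex. Seedlings grew on nutrient plates at 23 °C with 16 h of light and 8 h of dark per day. Wild type and epl1a/b had 2 libraries each, with 18796289 to 19088784 recovered reads per library. A separate pair of Col-0 libraries, 1 from plates kept in the dark and 1 from the light, had 18798088 and 27831231 counts. The series asks what the NuA4 complex contributes to chlorophyll synthesis and photosynthesis.

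The targeted genes were examined first. EPL1A (AT1G16690, TAIR10.1 chromosome 1, 5705897 to 5709563, plus strand) had a normalised count of 253 ± 39.7 (SD, n = 2) in wild type and 86.5 ± 10.3 (SD, n = 2) in the libraries labelled epl1a/b. Its log2 change was -1.54 ± 0.16 (SE; limma adjusted p = 0.000233). EPL1B (AT1G79020, chromosome 1, 29727044 to 29730593, minus strand) went the other way. It had 343 ± 11.3 (SD, n = 2) in wild type and 4527 ± 182 (SD, n = 2) in the libraries labelled epl1a/b, a 13.2-fold higher level (log2 change 3.72 ± 0.07, SE; limma adjusted p = 7.41e-07). For EPL1B the mutant label was not borne out by a lower transcript level, so directions below are those of libraries labelled epl1a/b. Gene-level values do not show whether these transcripts are intact.

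**Figure D1:**
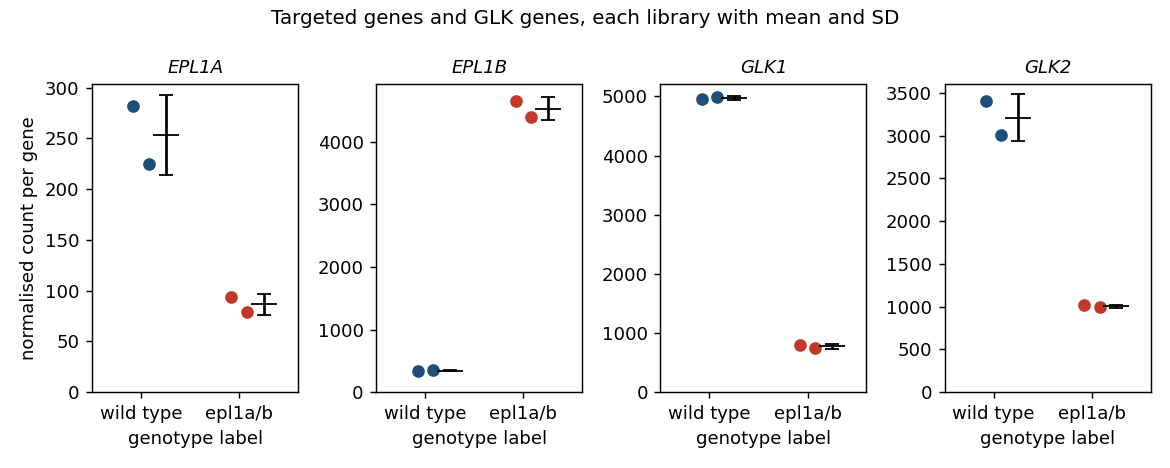
Normalised count per gene (linear axis from 0) of EPL1A, EPL1B, GLK1 and GLK2 in the 2 wild type and 2 epl1a/b libraries; points are libraries, and the dash with bars is the mean and SD. EPL1B stands at 4656 and 4399 in the epl1a/b libraries against 335 and 351 in wild type, while the other genes are lower there.

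Genes for chlorophyll synthesis and photosynthesis were lower in the libraries labelled epl1a/b, with list medians from 1.97-fold to 3.83-fold lower. Heat and oxidative stress genes were higher, with a median 2.90-fold higher. These lists passed camera at its preset correlation, and their adjusted p lay between 0.491 and 0.537 with an estimated correlation. In the libraries labelled epl1a/b, 5333 genes were higher and 5707 were lower among 23658 tested, and 1947 and 1890 of them changed by at least 2-fold. The largest falls included IRT1 (AT4G19690), the main root iron transporter, with 350 ± 116 (SD, n = 2) in wild type and 0 reads in both epl1a/b libraries, at least 133-fold lower. AT1G13650, an uncharacterised protein gene, had 1826 reads in wild type and 1 in epl1a/b. That is a ratio of 0.00144 on the log2(value + 1) scale, with a counting interval of 1.16e-05 to 0.00255 from the reads without an added value. BHLH100, an iron-deficiency transcription factor, had 371 reads against 1. Its ratio was 0.00709 on the log2(value + 1) scale, with an interval of 5.68e-05 to 0.0126 from the reads without an added value. The defensin-like gene AT1G13609 was 185-fold lower. NdhN, a subunit of the chloroplast NADH dehydrogenase-like complex, was 133-fold lower, and is uncertain because 25.4% of its exon bases overlap another gene.

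Among the largest rises, 3 genes had 0 reads in both wild type libraries. AT1G30170, which encodes a DUF295 protein, was at least 68.5-fold higher, and the defensin-like gene AT5G33355 at least 47.9-fold, the latter uncertain because 32.1% of its 50-base words occur elsewhere. HAC2, a histone acetyltransferase of the CBP family, was at least 29.6-fold higher. The small heat shock gene HSP17.6II rose 91.1-fold (log2 change 6.51 ± 0.35, SE; limma adjusted p = 7.84e-06). AT2G36255, another defensin-like gene, had 1 read in wild type and normalised counts of 82.8 and 141 in epl1a/b. Its ratio was 76.1 on the log2(value + 1) scale, with a counting interval of 38.0 to 8477 from the reads without an added value. Scaling to equal library totals moved the median log2 change of all genes from 0.02 to 0.25 and gave 8738 higher and 3650 lower genes, 70.5% higher against 48.3%. With one library left out, fewer samples gave 3288 higher genes without wild type replicate 1, 2905 without epl1a/b replicate 1 and 2660 without epl1a/b replicate 2.

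Genes for chlorophyll synthesis were lower as a group in the libraries labelled epl1a/b. Of 26 tested members, 24 fell, none rose and 2 did not pass, with 25 falling when adjusted over the list alone. The median log2 change was -1.46 (camera adjusted p = 2.08e-12), with adjusted p = 0.491 with an estimated correlation. The falls were largest in the light-dependent protochlorophyllide oxidoreductases. PORA was 27.5-fold lower (log2 change -4.78 ± 0.40, SE; limma adjusted p = 6.77e-05), PORC 12.8-fold lower and PORB 4.75-fold lower. HEMA2 and GUN4 were the 2 members that did not pass, with log2 changes of -0.24 and -0.66, and GUN4 is uncertain because 73.0% of its exon bases are overlapped.

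Light-harvesting antenna genes were also lower. Of 20 tested members, 18 fell and none rose, also when adjusted over the list alone, with a median log2 change of -1.94 (camera adjusted p = 3.33e-09), and adjusted p = 0.537 with an estimated correlation. LHCB1.4 went from 14414 ± 418 to 674 ± 205 (SD, n = 2 each), 21.9-fold lower. LHCA6 was 14.1-fold lower (limma adjusted p = 9.65e-07). LHCB2.3 was 22.0-fold lower and is uncertain, with 40.6% of its exon bases overlapped. LHCB4.3 and LHCB7, the 2 members that did not pass, had log2 changes of -0.17 and 0.14.

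The nuclear genes for photosystem and electron transport proteins were lower as a group. Of 35 members, 33 fell and none rose, also when adjusted over the list alone, with a median log2 change of -1.36 (camera adjusted p = 1.56e-13), and adjusted p = 0.537 with an estimated correlation. PSAD2, which docks ferredoxin at photosystem I, was 7.24-fold lower, the plastocyanin gene PETE1 was 4.28-fold lower, and the photosystem II gene PSBTN was 4.04-fold lower. The ferredoxin genes FD1 and FD2 did not pass, with log2 changes of -0.02 and 0.04. Of 20 Calvin-Benson cycle genes, 19 fell and 1 rose, also when adjusted over the list alone, with a median of -0.98 (camera adjusted p = 4.10e-08), and adjusted p = 0.491 with an estimated correlation. RBCS2B, a Rubisco small subunit gene, was 19.0-fold lower and is uncertain, with 21.4% of its 50-base words found in other genes. GAPA2 was 3.13-fold lower, and HCEF1 had a log2 change of -1.63 ± 0.07 (SE). The 1 member that rose was CP12-3, with a log2 change of 0.98 ± 0.14 (SE).

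**Figure D2:**
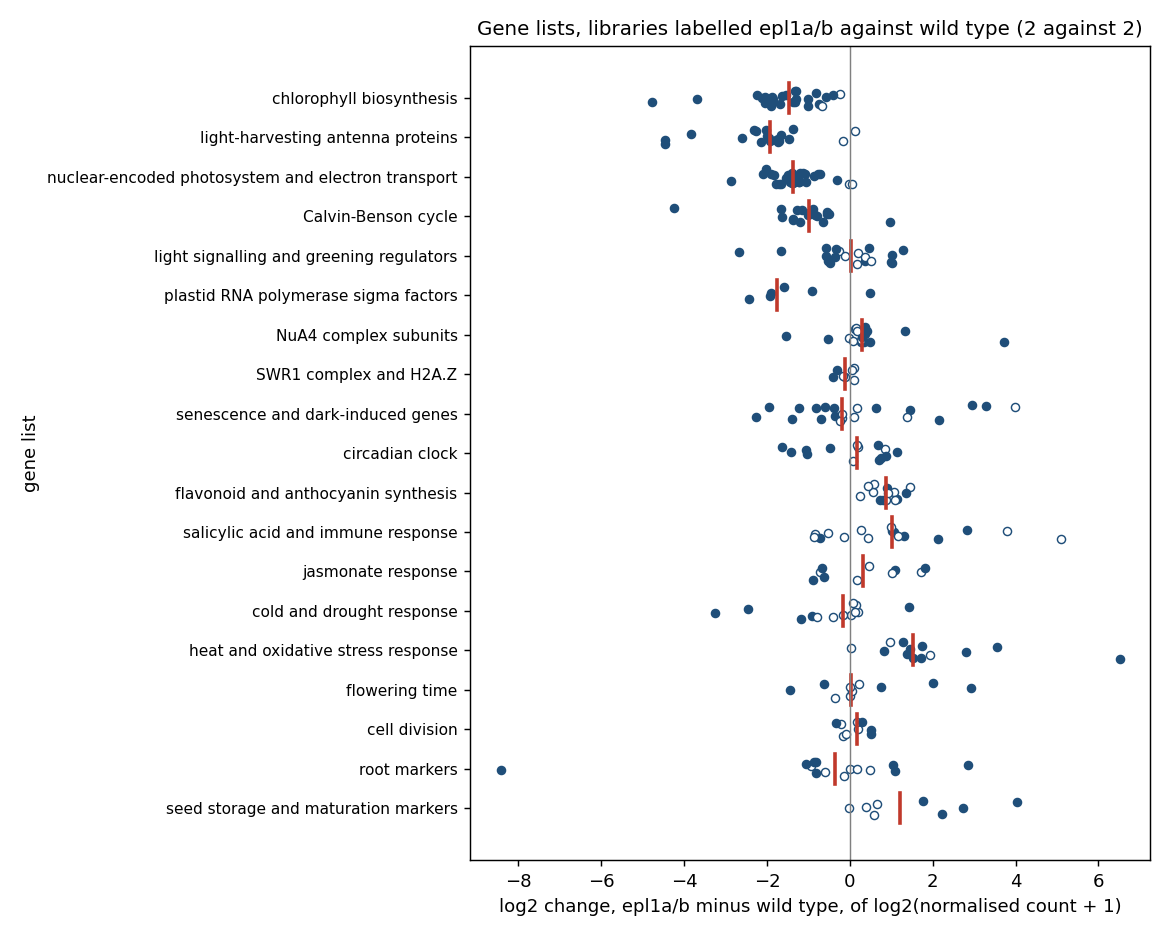
Log2 change of log2(normalised count + 1), epl1a/b minus wild type, of each tested member of the 19 gene lists; each point is a gene from 2 against 2 libraries, filled where its adjusted p is under 0.05, and the red bar is the list's median. The photosynthesis and chlorophyll lists have medians of -1.46, -1.94, -1.36 and -0.98.

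GLK1 and GLK2, transcription factors that activate photosynthesis genes, were among the regulators that fell. GLK1 (AT2G20570, chromosome 2, 8855302 to 8857758) went from 4970 ± 31.7 to 776 ± 42.1 (SD, n = 2 each), 6.40-fold lower (log2 change -2.68 ± 0.07, SE; limma adjusted p = 1.59e-06). GLK2 (AT5G44190, chromosome 5, 17798262 to 17800926) was 3.18-fold lower (log2 change -1.67 ± 0.08, SE). CGA1, a GATA factor that also promotes greening, rose 2.44-fold (limma adjusted p = 0.00139). Of 20 light signalling and greening regulators, 6 rose and 8 fell (7 and 9 when adjusted over the list alone), and the list did not pass (camera adjusted p = 0.781). Its median of 0.03 and mean of -0.06 differ in sign, and the mean was 0.18 on library totals. Of 6 sigma factors of the plastid RNA polymerase, 5 fell and 1 rose, also when adjusted over the list alone, with a median of -1.75 (camera adjusted p = 0.0134), and adjusted p = 0.614 with an estimated correlation. SIG4 was 5.38-fold lower and SIG3 3.79-fold lower, while SIG5 rose by 0.49 in log2.

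Genes for NuA4 subunits were mostly higher. Of 18 members, 10 rose and 2 fell (11 and 2 when adjusted over the list alone), with a median log2 change of 0.28 (camera adjusted p = 0.0165) and adjusted p = 0.491 with an estimated correlation. YAF9B had a log2 change of 1.32 ± 0.26 (SE), and YAF9A, of the same family, fell by 0.53 on the log2 scale. Without EPL1A and EPL1B, 9 of 16 rose and 1 fell (camera adjusted p = 0.0147), and p = 0.102 before adjustment with an estimated correlation. Without wild type replicate 2 the full list did not pass (adjusted p = 0.0613, the highest over 13 alternatives at the preset correlation, with 0.0146 the lowest). Of 7 genes for the SWR1 complex and the histone variant H2A.Z, none rose and 2 fell, 1 of them when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.781). HTA9, an H2A.Z gene, had a log2 change of -0.40 ± 0.10 (SE; limma adjusted p = 0.0147), and the SWR1 subunit gene ARP6 one of -0.30 ± 0.10 (SE; limma adjusted p = 0.0362). The HTA9 call was lost without wild type replicate 1 (log2 change -0.35), wild type replicate 2 (-0.45) or epl1a/b replicate 2 (-0.26). The ARP6 call was lost without wild type replicate 1 (-0.20), epl1a/b replicate 1 (-0.34) or epl1a/b replicate 2 (-0.26), and with crossed pairing of the replicates (adjusted p = 0.0514), the edgeR exact test (0.0571) or DESeq2 (0.134). On library totals both calls were lost, with log2 changes of -0.16 and -0.06.

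Heat and oxidative stress genes rose. Of 13 members, 10 rose and none fell (11 and none when adjusted over the list alone), with a median log2 change of 1.54, or 1.44 with the member at 0 in wild type held at its bound (camera adjusted p = 3.47e-05), and adjusted p = 0.537 with an estimated correlation. Beside HSP17.6II, HSP21 rose 11.7-fold (log2 change 3.55 ± 0.57, SE; limma adjusted p = 0.00177), a call lost without epl1a/b replicate 1 (log2 change 2.92) and kept without epl1a/b replicate 2 (4.17).

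Flavonoid and anthocyanin genes were higher, with 5 of 14 rising and none falling, also when adjusted over the list alone, and a median of 0.88 (camera adjusted p = 0.0134), and adjusted p = 0.868 with an estimated correlation. MYB12, a flavonol regulator, rose 2.54-fold. The flavonol synthase gene FLS1 rose 2.21-fold, and its call was lost without wild type replicate 1 (log2 change 0.92). The flavonoid list itself did not pass without wild type replicate 1 (median 0.45, adjusted p = 0.0815) or on library totals (median 1.12, adjusted p = 0.0828). Its median was 1.35 without wild type replicate 2, and its adjusted p ranged down to 2.26e-05 over 13 alternatives. Of 8 seed storage and maturation markers that could be tested, 4 rose and none fell, also when adjusted over the list alone, with a median of 1.21 (camera adjusted p = 0.0134), and adjusted p = 0.491 with an estimated correlation. That median was 2.21 with a filter of 10, 1.98 with a pseudocount of 0.1 and 0.65 with no filter. The list did not pass on library totals (adjusted p = 0.0828, the highest of 13 alternatives, with 0.00252 the lowest). The albumin gene SESA4 had 2 reads in wild type and 75 in epl1a/b, a ratio of 16.5 on the log2(value + 1) scale with a counting interval of 8.37 to 263. LEC2, a regulator of embryo development, had a log2 change of 2.73 ± 0.82 (SE), and its call was lost without wild type replicate 1 (1.45), epl1a/b replicate 1 (2.73) or epl1a/b replicate 2 (2.73), and kept without wild type replicate 2 (4.01). It was also lost with a pseudocount of 0.1 (4.24) and with DESeq2 on recovered reads (2.61).

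The other lists did not pass and held members going both ways. Of 21 senescence and dark-induced genes, 5 rose and 9 fell, also when adjusted over the list alone (camera adjusted p = 0.683), with a median of -0.20 and a mean of 0.28. DIN11 rose 9.78-fold (log2 change 3.29), with 2.70 without epl1a/b replicate 1 and 3.88 without epl1a/b replicate 2. DIN2 rose 7.74-fold (2.95), with 3.67 and 2.24 without them, and on recovered reads limma-voom called neither DIN11 (adjusted p = 0.0516) nor DIN2 (adjusted p = 0.176). The edgeR quasi-likelihood test did not call DIN2 either (adjusted p = 0.0622). NAP, a senescence transcription factor, was 4.79-fold lower. Of 14 clock genes, 5 rose and 5 fell (6 and 5 when adjusted over the list alone; camera adjusted p = 0.781), with a median of 0.18 and a mean of -0.01, or 0.22 on library totals. The morning genes RVE8 and LHY were 3.11-fold and 2.68-fold lower. Of 10 flowering time genes, 3 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.882). FLC, a repressor of flowering, had a log2 change of 2.92 ± 0.50 (SE) from 8 and 82 reads. It is uncertain because 68.1% of its exon bases are overlapped, and its call was lost without epl1a/b replicate 1 (2.63), with 3.54 without wild type replicate 1 and 2.31 without wild type replicate 2. MAF4, of the same family, had a log2 change of 2.01 ± 0.43 (SE), lost without epl1a/b replicate 1 (2.05) or epl1a/b replicate 2 (1.96), with 2.68 without wild type replicate 1 and 1.34 without wild type replicate 2.

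Of 16 salicylic acid and immune genes, 5 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.442). The list passed without epl1a/b replicate 2 (adjusted p = 0.00894, the lowest of 13 alternatives, with 0.961 the highest), and PR1, a salicylic acid marker, had 1716 in epl1a/b replicate 1 and 95.4 in replicate 2. PR5 rose 4.34-fold. CYP71A13, a camalexin synthesis gene, had 3 reads in wild type and 33 in epl1a/b, a ratio of 7.13 on the log2(value + 1) scale with a counting interval of 2.88 to 46.8. It is uncertain because 22.1% of its exon bases are overlapped. Its call was lost without wild type replicate 1 (log2 change 1.83), epl1a/b replicate 1 (2.34) or epl1a/b replicate 2 (3.33), and kept without wild type replicate 2 (3.83). It was also lost with a pseudocount of 0.1 (4.45). Of 10 jasmonate genes, 2 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.881). JAZ1 rose 2.14-fold. JAZ5 rose 3.51-fold, a call lost without wild type replicate 1 (log2 change 1.82) or wild type replicate 2 (1.80). Of 13 cold and drought genes, 1 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.442). COR15A was 9.50-fold lower and COR15B 5.53-fold lower, the latter uncertain because 29.6% of its exon bases are overlapped. The log2 change of COR15B was -1.86 without wild type replicate 1 and -3.07 without wild type replicate 2. Of 9 cell division genes, 3 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.781). CYCB1;1 had a log2 change of 0.51, lost without wild type replicate 1 (0.30), epl1a/b replicate 1 (0.56) or epl1a/b replicate 2 (0.47), and with DESeq2 on recovered reads (0.51). AUR1 had 0.50, lost without wild type replicate 1 (0.43), wild type replicate 2 (0.57) or epl1a/b replicate 2 (0.36). Of 14 root markers, 3 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 0.781), with IRT1 lower as above and the nitrate transporter NRT2.1 7.22-fold higher.

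The dark and light libraries of Col-0 were compared as values of 1 library each, with no replicate check. Storage protein and oleosin transcripts summed to 6959 CPM in the dark library and 26.2 CPM in the light one. Stage or material of the samples may therefore differ too, and no dark ratio below is separated from that. Photosynthesis genes were far lower in the dark library. The antenna list had a median log2 ratio of dark over light of -3.59, the photosystem and electron transport list -3.28, the Calvin-Benson list -2.56 and the chlorophyll synthesis list -1.58, each at percentile 0 among 10000 matched random lists. LHCB1.4 had 11.8 CPM in the dark and 4555 CPM in the light (log2 ratio -8.58, interval -8.78 to -8.41), and LHCB1.1 29.7 and 7209 CPM, uncertain because 20.5% of its 50-base words occur elsewhere. PSAN, ATPD, RBCS1B, GAPA2 and CHLI1 had log2 ratios of -5.16, -4.35, -5.34, -4.56 and -3.01. PORA went against its list, with 1027 CPM in the dark and 3.85 CPM in the light (log2 ratio 8.03, interval 7.78 to 8.36). GLK1 and GLK2 had log2 ratios of -2.31 and -2.41. EPL1A had 162 counts in the dark and 213 in the light, and EPL1B 185 and 259, both with intervals that include 0.

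**Figure D3:**
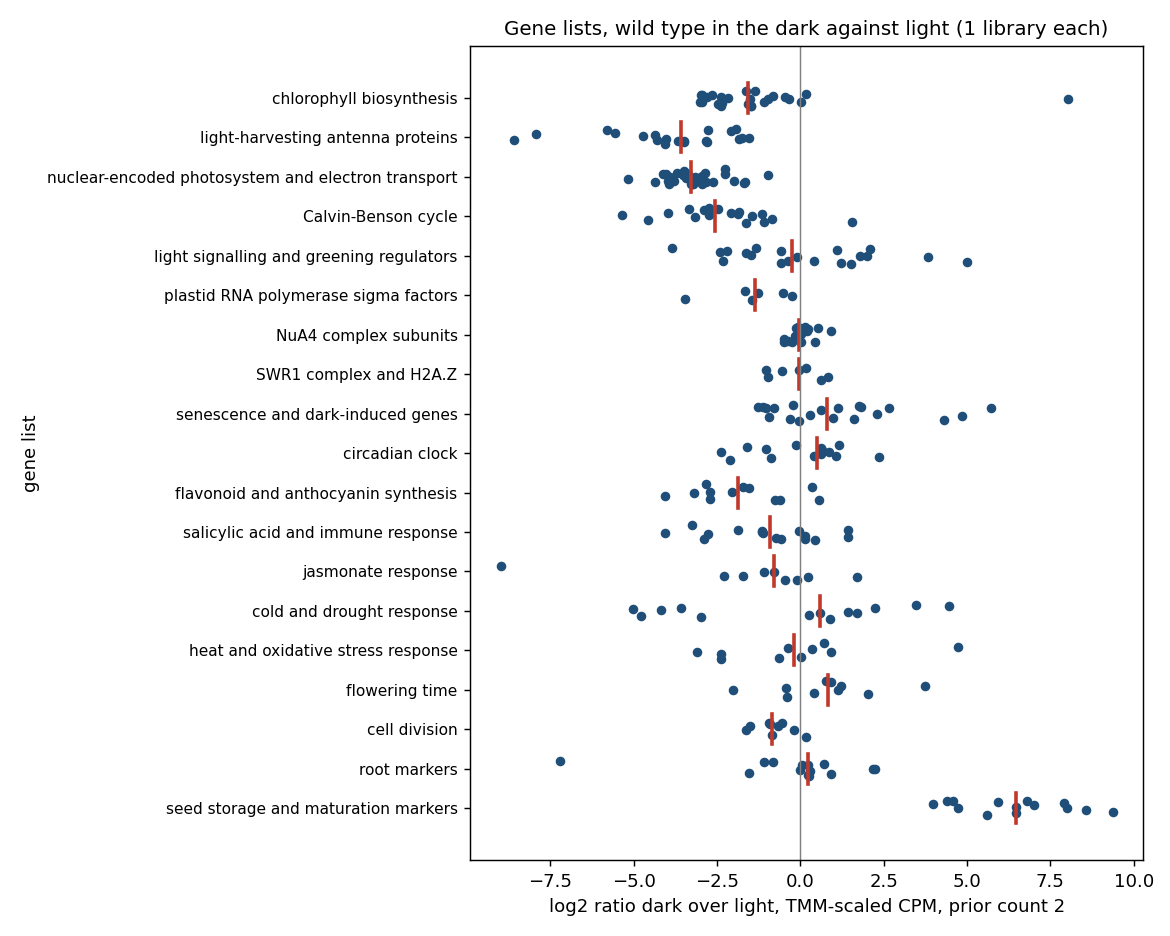
Log2 ratio of dark over light (TMM-scaled CPM, prior count of 2) of each measured member of the 19 lists, from 1 library per condition; each point is a gene and the red bar the list's median. The seed list has a median of 6.47 and the antenna list one of -3.59.

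Seed storage and maturation transcripts were the other extreme. All 14 measured members were at least 2-fold higher in the dark library, with a median of 6.47 (percentile 100). The cruciferin genes CRC and CRB had log2 ratios of 9.37 and 8.56. The 5 highest ratios also held the glycine-rich protein genes AT2G05580 (9.41) and AT5G35660 (9.19) and the polyketide cyclase gene AT1G14950, which had 1 count in the light. The 5 lowest held LHCB1.4, the lipoxygenase gene LOX2 (-8.98) and the glucosinolate synthesis genes CYP79F1, CYP83A1 and BCAT4. CYP79F1 had 1 count in the dark and 5160 in the light, with an interval of -17.30 to -9.51. CYP83A1 had a log2 ratio of -8.97 and BCAT4 one of -8.15, the latter uncertain because 21.2% of its exon bases are overlapped.

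Among the other lists, 6 more lay outside the central 95% of random lists. Senescence and dark-induced genes had a median of 0.81 (percentile 99.97), with BCAT2 at 5.73 and DIN6 at 4.85. Flowering time genes had 0.84 (percentile 98.8), with FLC at 2.03, uncertain as above, and SVP at -2.01. Flavonoid genes had -1.88 (percentile 0), with DFR at -4.04 and UGT75C1 at -2.82, the latter uncertain because 27.1% of its exon bases are overlapped. Sigma factors had -1.35 (percentile 0.37), with SIG5 at -3.45 and SIG2 at -1.67. Salicylic acid genes had -0.92 (percentile 2.2, or 2.66 and so within it among genes with at least 50 summed counts), with EDS5 at 1.42 and PAD4 at -1.16. Cell division genes had -0.83 (percentile 2.09), with MCM2 at -1.64 and PCNA1 at -1.50.

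The remaining 8 lists lay within it. Clock genes were at percentile 97.04, with LHY at 2.37 and PRR9 at -2.39, the latter uncertain because 28.6% of its 50-base words occur elsewhere. Cold and drought genes were at percentile 96.9, with RD29B at 4.45 and CBF1 at -5.01. Root markers were at percentile 80.1, with CASP1 at 2.25. NRT2.1 had 0 counts in the dark and 331 in the light, at least 87.2-fold lower in the dark. Light signalling regulators were at percentile 13.4, with PIL1 31.9-fold higher in the dark and HFR1 at 3.83. Jasmonate genes were at percentile 3.64, with VSP2 at -2.30, and heat and oxidative stress genes at 33.5, with ZAT12 at -3.10 and BAP1 at -2.39. The SWR1 and H2A.Z list was at percentile 45.1, with HTA8 at -1.04 and HTA11 at -0.97. The NuA4 list was at percentile 39.1, with EAF6 at 0.91 and MRG1 at 0.52.

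Across genes, the change in libraries labelled epl1a/b and the change in the dark were compared. Spearman's rho across the 20968 genes in both tables was 0.07 and Pearson's r was 0.11, and rho was 0.14 over the 11626 genes with a mean of at least 10 CPM in both tables; genes are not independent replicates, so no p-value is given. Of 10445 called genes, 51.3% changed in the same direction in the dark, against 50.3% for independent signs. Of 95 called members of the 4 photosynthesis and chlorophyll lists, 97.9% had the same direction, against 95.9% for independent signs, since nearly all were lower in both. PORA was 1 of the 2 that fell in epl1a/b and were higher in the dark.

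**Figure D4:**
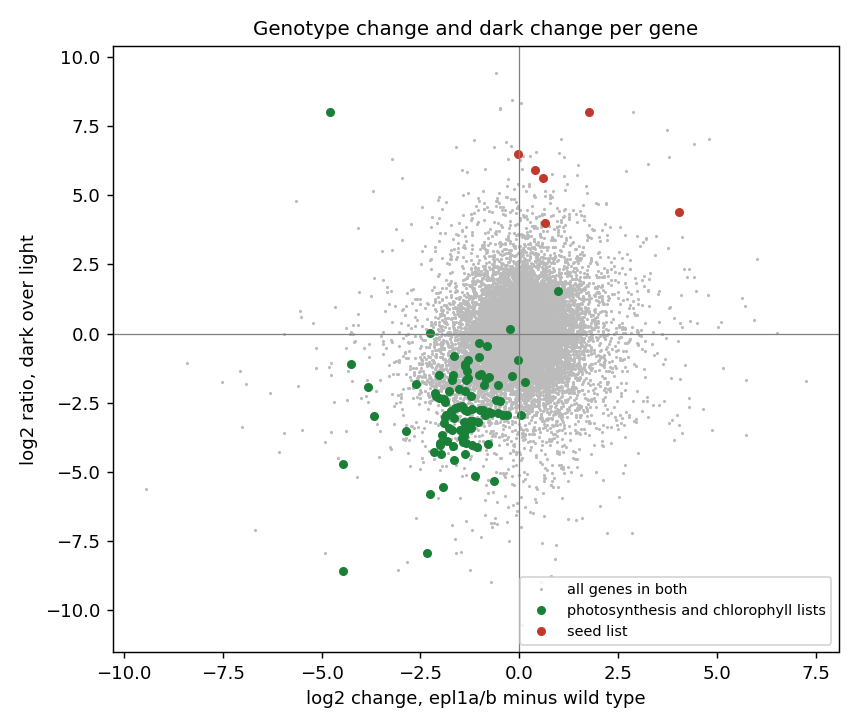
Log2 change in libraries labelled epl1a/b (2 against 2, horizontal) and log2 ratio of dark over light (1 library each, vertical) for the 20968 genes in both tables, with the photosynthesis and chlorophyll lists in green and the seed list in red. Most green points lie lower in both, and PORA is the green point at -4.78 and 8.03.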

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

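The recovered-read tests, the filter of 10, the crossed pairing and the NuA4 list without EPL1A and EPL1B were chosen after seeing the data. With 2 libraries per genotype, leaving 1 out assumes that the lone library varies like the other genotype. Requiring an absolute log2 change of at least 1 left 1947 higher and 1890 lower genes, as that limit drops smaller changes. Library totals gave 8738 higher and 3650 lower, with 81.4% of the main calls kept and the median of all genes at 0.25. Leaving out each replicate gave 2660 to 3689 higher and 3836 to 4147 lower, with fewer samples. The other scalings, filters, pseudocounts and tests stayed within 1.5 times the main counts, from 3938 higher and 4432 lower with DESeq2 on recovered reads to 5448 higher and 5759 lower. No called gene reversed under any setting and stayed called. Same-numbered libraries did not deviate together (correlation of deviations -0.14, 2 pairs). Over the 17270 genes with a mean of at least 50 it was -0.24. The negative sign means that opposite-numbered libraries tended to deviate in the same direction, and its cause was not tested. The replicate block gave 4578 higher and 5099 lower genes, and crossed pairing gave 5353 and 5585.

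EPL1A and EPL1B kept their direction and call under all settings run. Of the named genes' alternative fits, 750 kept direction and call and 37 lost the call. Of the lists' fits, 245 kept both, 13 lost the call, 1 gained it and 7 changed the sign of the mean log2 change. With an estimated correlation, 0 of 9 lists remained called, and 0 lists had an unadjusted p under 0.05. The NuA4 and seed lists lost their calls too, though their estimated correlations were -0.031 and -0.139. Correlation among members therefore does not account for the losses of those lists. The other called lists had estimated correlations above the preset one, from 0.146 for the Calvin-Benson list to 0.618 for the antenna list. Their p-values at the preset correlation depend on that setting, and correlation among members may account for part of their losses. Camera with an estimated correlation also takes its degrees of freedom from the few libraries, so a lost call is weak evidence against a list. For lists with a positive estimate the 2 contributions were not separated. The 7 sign changes were in lists called under neither setting. On library totals they were light signalling (0.18), SWR1 and H2A.Z (0.13) and the clock (0.22). Leaving out each replicate gave -0.12 to 0.00038 for light signalling, -0.064 to 0.037 for the clock (0.0033 without wild type replicate 1, 0.037 without epl1a/b replicate 1) and -0.74 to 0.080 for root markers. The cause was not tested. Dark lists outside the central 95% numbered 10 to 11, and of the medians of all 19 lists over 4 alternatives, 66 stayed within counting error and 10 moved. Spearman's rho rose from 0.07 to 0.14 over the 11626 genes with a mean of at least 10 CPM in both tables, the cause was not tested, and was 0.06 to 0.08 otherwise. Leaving out plastid and mitochondrial genes was not run, since neither table lists any.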

Other observations

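Except for the tests of scaling and those of the iron list without IRT1 and the nitrate list without NRT2.1, the tests of explanations below were chosen only after the result was seen, and the 2 added lists and 8 product families were chosen after seeing the data. Because IRT1 and BHLH100 stood among the largest falls, a list of iron deficiency genes was tested. Of 18 tested members, 13 fell and 3 rose in the libraries labelled epl1a/b, and without IRT1 the median log2 change was -2.52 (camera p = 0.00114, or p = 0.125 with an estimated correlation). Without both genes that prompted the list, 11 of 16 fell and 3 rose, with a median of -1.96 (camera p = 0.00306, or p = 0.167 with an estimated correlation). bHLH38 had 239 reads in wild type and 0 in epl1a/b, at least 47.6-fold lower, and AT2G30766 had 2164 and 19. Both are uncertain, with 35.7% and 20.45% of their exon bases overlapped. BHLH101 had a log2 change of -4.19, and the ferric reductase gene FRO2 had 271 and 47. FRU, which activates IRT1, rose 1.90-fold (limma adjusted p = 0.0109). The fall of IRT1 is consistent with a lower expression of iron deficiency genes as a set (median -1.96 without both prompting genes), a hypothesis that the estimated correlation leaves open and that comes from the same data. Of 7 other nitrate uptake and assimilation genes, 3 rose and 2 fell with a median of 0.17. That lies below 0.5, the bound set before the result was seen for reading the list as not moving with NRT2.1. The reading was changed to undecided after the result was seen, because a median over members that went both ways decides nothing. NIA1, a nitrate reductase gene, and the nitrite reductase gene NIR1 rose 1.83-fold and 1.90-fold, and NRT1.1 was 1.76-fold lower.

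Among 8 product families, WRKY transcription factors were higher, with 24 of 64 rising and 2 falling (camera adjusted p = 0.000281, and adjusted p = 0.454 with an estimated correlation). Glutathione S-transferases (23 rose, 5 fell, of 51; adjusted p = 0.0112), peroxidases (24 rose, 8 fell, of 59; adjusted p = 0.0112) and defensins (10 rose, 3 fell, of 32; adjusted p = 0.0408) were also higher, with adjusted p = 0.454, 0.475 and 0.454 with an estimated correlation. Pentatricopeptide repeat proteins (18 rose, 62 fell, of 241; adjusted p = 0.00608) and TIR-NBS-LRR proteins (14 rose, 34 fell, of 99; adjusted p = 0.0273) were lower, with adjusted p = 0.454 and 0.544 with an estimated correlation. Over all 23658 tested genes, 5333 rose and 5707 fell. The share of pentatricopeptide repeat genes that fell was close to that of all genes, and their share of rises was smaller. Cytochromes P450 (69 rose, 51 fell, of 205; adjusted p = 0.156) and auxin-responsive proteins (18 rose, 30 fell, of 92; adjusted p = 0.178) did not pass. On library totals, which moved the median of all genes to 0.25, the pentatricopeptide repeat median went from -0.21 to 0.03, with 42 rising and 47 falling, the TIR-NBS-LRR one from -0.27 to -0.04, with 21 rising and 24 falling, and the auxin-responsive one from -0.23 to 0.01, with 22 rising and 24 falling. In that scaling 37 WRKY genes rose and none fell, 27 glutathione S-transferases rose and 3 fell, 31 peroxidases rose and 4 fell, 85 cytochromes P450 rose and 36 fell, and 11 defensins rose and 3 fell. Defensins then did not pass (adjusted p = 0.475) and auxin-responsive proteins did, as lower than other genes (adjusted p = 0.0317). The families were not run with a library left out.

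EPL1B was higher in the libraries labelled epl1a/b. Shared reads are argued against by 0 of its 2085 exon words of 50 bases being found in EPL1A. Read-through from a changed neighbourhood is argued against by 0 of 5 tested genes within 10 kb rising by a log2 change of 1, the highest being -0.02. Exchanged genotype labels are argued against by the EPL1B to EPL1A ratio, which was 1.14 and 1.22 in the dark and light Col-0 libraries, 1.19 and 1.56 in wild type, and 49.7 and 55.5 in epl1a/b. A transcript driven from an insertion or transgene in the line was not tested and stays open, as does an effect of the mutation.

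Photosynthesis and chlorophyll genes were lower in the libraries labelled epl1a/b. Of the 101 members, 68.3% lay more than 3 standard errors from their median, so they did not all fall alike. A smaller share of green tissue is not decided by that, because members' levels in other tissues were not measured. Other changes could also add to it, so it stays open. The authors' scaling is argued against by a median of -1.13 on library totals. Harvest at another time of day also stays open: evening clock genes lay 2.08 above morning clock genes in log2 change, which a changed clock in the mutant would give as well. An effect of the genotype is the difference the design names, and it was separated from neither time of harvest nor the share of green tissue.

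Seed storage transcripts were high in the dark library. Scaling is argued against by a median log2 ratio of 6.69 on library totals. Seed or seed coat material in the dark sample and a younger or slower seedling cannot be told apart with 1 library per condition. That 10 of 10 storage protein and oleosin genes had at least 10 counts there follows from the pattern itself and decides nothing, and their summed level was 6959 CPM in the dark and 26.2 CPM in the light. The dark treatment is the difference the design names, and it stays open and untested.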
